A study of Mus musculus with 16 samples.

How the data were processed

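CD4+ T cells were sorted from the mediastinal lymph nodes of male BALB/c mice, 8 to 12 weeks old, on day 7 after ligation of the left anterior descending coronary artery or after a sham thoracotomy. Per the labels, TCRM cells are Thy1.1 myosin-specific CD4+ T cells from T cell receptor transgenic donors, given to the recipients before the operation, and ENDO cells are the recipients' own CD4+ T cells from those animals. Sorting purity was above 98% per the labels' protocols. RNA was amplified and hybridised to Affymetrix whole transcript arrays. The 16 arrays fall into TCRM infarction (n = 5), TCRM sham (n = 3), ENDO infarction (n = 5) and ENDO sham (n = 3). The number of arrays limits the precision.

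The deposited value table holds log2 signal for 41345 probe sets on 16 arrays. Affymetrix Expression Console and Transcriptome Analysis Console are named in the submitters' processing notes, and their versions and the summarisation method are not given in the sources used here. Exact values shared by arrays exceeded those of chance by 119.6 ± 57.8 (SD, 28 pairs) between TCRM arrays and by 118.1 ± 71.8 (SD, 28 pairs) between ENDO arrays. Between TCRM and ENDO arrays the excess was -6.1 ± 40.5 (SD, 64 pairs), so the populations were treated as normalized separately. Levels of TCRM and ENDO cells were therefore not tested against each other, although that test had been planned after infarction and after sham operation. The comparison of responses uses differences taken within each population.

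The authors also deposited a table per population, headed as 2-fold with p under 0.05, with averages on the log2 scale, a fold, a p-value and a false discovery rate. Decimal commas were read as points, and 4 ENDO fold cells contradicted their averages. Directions and ranks of the authors' genes were therefore taken from the averages and not from the fold cells. These tables give the symbols used here. Of their 468 probe sets, 270 had 1 symbol, 18 had several and 180 had none, and all other probe sets are unnamed here. No gene was named from a probe set with several symbols. Of 269 distinct symbols, 207 were found in the GRCm38.p6 RefSeq gene table and 10 only as a synonym.

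The source names of the arrays titled infarction 5 say sham, while their titles say infarction. Averages over the groups of the titles equalled the authors' averages within 0.01 in 196 of 196 TCRM and 274 of 274 ENDO probe sets. Averages over the groups of the source names did so in 2 of 196 and 8 of 274. The titles were used.

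Probe sets under the 30th percentile of mean signal (log2 4.721) were left out, which removed 12404 and left 28941. A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), and 2-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. Among the tested probe sets, 1060 had values identical to another. The planned choice of 1 probe set per gene, the mean of a gene's probe sets and the camera and fry tests of gene lists need symbols for all probe sets and were not run. The 27 gene lists fixed gene by gene before the data were examined hold 588 genes, of which 29 were named. Their counts cover named members only, which the authors had selected on these arrays, so they are not independent evidence of direction. Adjustment over the list alone covers those members. A further list fixed beforehand, of all T cell receptor variable segments, was not analysed.

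Genes were named by a rule fixed before the data were examined. It takes up to 10 rises and 10 falls past the threshold, up to 4 members of each list with the lowest p, a set of genes of interest where named, and up to 10 genes per direction with the highest fold in the authors' tables. Gene models, clones and receptor segments were left unnamed. Of the genes of interest, Il4 and Pdcd1 were named and the others were not analysed here.

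Per the series design, both populations came from the same animals, and the labels use the same numbers in both. Deviations of arrays with the same number correlated between -0.089 and 0.077 over 8 pairs, and 0 of 8 were above 0.1. That a number stands for an animal is not stated, so fits with the number as a block were run as alternatives. Other alternatives were the filter, scaling, spread, array weights, thresholds, the source name labels, each array left out in turn and the arrays of 1 population alone. Weights and spreads per population, identical probe sets counted once, outlying arrays left out and scaling within a population were chosen after seeing the data.

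The fit was tested on simulated data with the real means, each population's own spread and 200 changed probe sets per population among 28941. The simulated noise was independent between probe sets, so the shares of false calls leave out any structure shared across an array. In TCRM cells it recovered 76% of the 50 changes of 1 on the log2 scale and 94% of the 50 changes of 2, and 7.3% of calls were false. In ENDO cells it recovered 60% and 98%, and 36.4% of calls were false. Fitted to the 8 ENDO arrays alone it recovered 38% and 86%, with 3.4% false calls. For the difference of responses it recovered 43% and 90% of 100 changes each, with 8.4% false calls.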

Results

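Whole transcript array signal was measured in 2 populations of CD4+ T cells from the mediastinal lymph nodes, which drain the heart, on day 7 after myocardial infarction or sham operation. TCRM cells carry a transgenic receptor for cardiac myosin and had been transferred into the mice, and ENDO cells were the recipients' own. There were 5 infarction and 3 sham arrays of each population. Median log2 signal lay between 5.37 and 5.43 on the TCRM arrays and between 5.61 and 5.79 on the ENDO arrays. The mean correlation of an array with the others of its population was 0.935 to 0.968 for TCRM and 0.824 to 0.931 for ENDO cells. ENDO infarction array 5 had the lowest value, 0.824. The median residual SD was 0.197 in TCRM and 0.272 in ENDO cells.

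**Figure D1:**
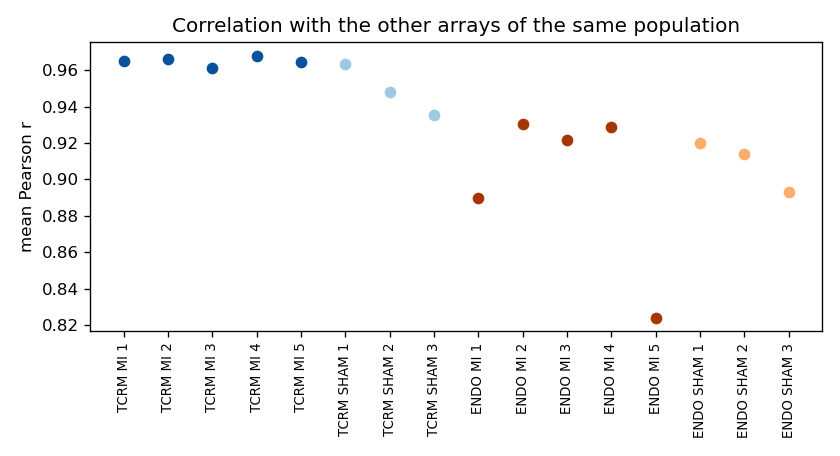
Mean Pearson correlation, over probe sets, of each array with the other 7 arrays of its population; each point is an array, coloured by group, and the vertical axis does not start at 0. TCRM arrays lie between 0.935 and 0.968, and ENDO infarction array 5 lies lowest at 0.824.

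The comparison of TCRM cells asked which transcripts differed in myosin-specific cells after infarction. Il21 (interleukin 21, a cytokine of helper T cells that acts on B cells) rose by 3.19 ± 0.30 (log2, SE) and Tigit (an inhibitory receptor) by 3.10 ± 0.28. Sccpdh rose by 3.40 ± 0.34, Gpm6b (a membrane glycoprotein) by 3.30 ± 0.34 and Csf1 (the macrophage colony-stimulating factor) by 2.28 ± 0.26. For each of these genes all 5 infarction arrays lay above all 3 sham arrays, and limma's adjusted p was between 0.000146 and 0.000433. Such separation held for all 219 probe sets that passed in TCRM cells, so it does not set these genes apart. Mean Il21 signal was 7.98 ± 0.52 (log2, SD, n = 5) after infarction and 4.79 ± 0.71 (SD, n = 3) after sham operation.

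Of 28941 probe sets, 219 changed, 193 upwards and 26 downwards, and 92 of them could be named. Other rises were Angptl2 (2.37 ± 0.22), Egln3 (2.36 ± 0.35, a prolyl hydroxylase of the hypoxia response) and Gpr155 (2.33 ± 0.24), with log2 differences and SE. Stfa3 rose by 4.62 ± 0.34 and Art2a-ps by 2.39 ± 0.24, but both have closely similar paralogs and their identity is uncertain. Mean sham signal was 4.49 for Sccpdh and 3.83 for Stfa3, under the filter cutoff of 4.721, and 4.79 for Il21, just above it. As signal over background is not known, the sizes of these differences are uncertain. The size for Gpm6b is uncertain too, as its sham mean was 5.55 ± 0.94 (SD, n = 3) and the authors' sham average was 6.09. Its rise was 9.86-fold here and 6.85-fold in the authors' table. Named falls were Arhgap29 (-1.39 ± 0.27), Enpp4 (-1.29 ± 0.22) and Amigo2 (-0.94 ± 0.19).

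Of the 22 genes on the follicular helper T cell list 7 were named. All 7 rose, and 7 passed when adjusted over the list alone. They include Il21, Gpm6b, Maf (2.02 ± 0.23, a transcription factor), Pdcd1 (1.97 ± 0.30, the inhibitory receptor PD-1) and Il4 (2.04 ± 0.23, a cytokine). All 4 named genes of the list of inhibitory receptors, exhaustion and anergy rose, among them Nt5e (1.93 ± 0.24, the ectoenzyme CD73) and Nrp1 (1.36 ± 0.29), and 4 passed over the list alone. Of 4 named regulatory T cell genes, Tigit, Nt5e and Nrp1 rose and Prdm1 did not pass (0.85 ± 0.19, adjusted p = 0.0616). Of 7 named cytokine genes 5 rose, including Tgfb3 (1.72 ± 0.22), and 7 passed over the list alone. Of 9 named effector and memory genes 4 rose, including Cxcr3 (1.17 ± 0.14, a chemokine receptor), Anxa2 (1.31 ± 0.20) and S100a4 (1.40 ± 0.28), and 9 passed over the list alone. The authors had selected all these members as at least 2-fold changed with p under 0.05 on these arrays, so the counts are not independent evidence of direction, and passing over the list alone was fixed by that selection. Of 160 distinct named genes 122 were higher after infarction in the authors' TCRM table. Fisher's exact test of the lists against the other named genes gave no adjusted p under 0.05 (follicular helper list, p = 0.199, adjusted p = 0.398). In each list tested all named members were already higher, so no lower p was possible in that direction. The test therefore cannot decide whether any list stands apart. Several genes, such as Maf, Il4, Il21 and Tigit, are on more than 1 list. The full lists hold 27 genes for inhibitory receptors, exhaustion and anergy, 30 for regulatory T cells, 41 for cytokines and 25 for effector and memory cells. Members outside the authors' tables could not be seen, so the counts do not describe whole lists.

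All 3 named Th2 genes rose (Maf, Il4 and Nfil3, the last by 1.24 ± 0.24), as did both named Th17 genes (Il21 and Il1r1, the latter by 1.51 ± 0.32). Of 2 named Th1 genes Cxcr3 rose and Ccl5 did not pass (1.31 ± 0.35, adjusted p = 0.121). Timp2 of the extracellular matrix list rose by 0.97 ± 0.16. Among markers of other cells, Cd22 of the B cell list rose by 1.17 ± 0.15, while Nkg7 of the CD8 and NK list (1.06 ± 0.24, adjusted p = 0.0686) and Prdm1 of the plasma cell list did not pass. Trat1 of the T cell identity list (-1.10 ± 0.27, adjusted p = 0.0963) and Mcm2 of the cell cycle list (0.15 ± 0.25) did not pass. The other 11 lists had no named member.

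In the authors' deposited table for TCRM cells, 153 probe sets were higher and 43 lower after infarction, and 1 had a false discovery rate under 0.05 (Cd38, 0.0413). Of the 196, 179 were tested here and 103 changed. With the 8 TCRM arrays alone 118 probe sets changed, 107 upwards, and 10 of 27 named genes that had passed no longer did (Amigo2, Anxa2, Arhgap29, Egln3, Il1r1, Nfil3, Nrp1, Pdcd1, S100a4 and Timp2). The count was 127 without TCRM infarction array 1, 124 without infarction array 2, 113 without sham array 2 and 127 without sham array 3, and 0 (2051 at unadjusted p under 0.05) with infarction array 5 counted as sham. Amigo2, Arhgap29, Enpp4, Il1r1, Nfil3, Nrp1, S100a4 and Timp2 no longer passed with at least 1 of the TCRM arrays left out.

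**Figure D2:**
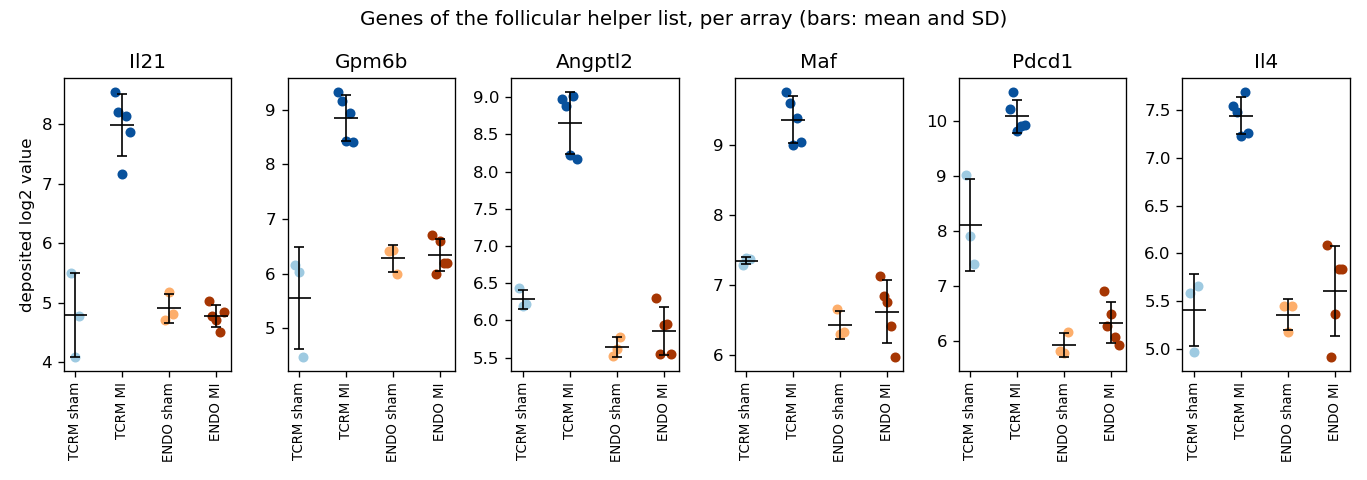
Deposited log2 signal of 6 genes of the follicular helper list, with a point per array, the mean and the SD, for TCRM sham (n = 3), TCRM infarction (n = 5), ENDO sham (n = 3) and ENDO infarction (n = 5); vertical axes differ and do not start at 0. TCRM infarction arrays lie above TCRM sham arrays for each gene, and levels of TCRM and ENDO cells are not comparable because the populations were treated as normalized separately.

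The comparison of ENDO cells asked the same question of the recipients' own CD4+ T cells. In the planned fit Cdkn2d (an inhibitor of cyclin-dependent kinases) was higher after infarction by 1.49 ± 0.24 (log2, SE) and Dnajc9 by 0.92 ± 0.15. Ppp1ca (a catalytic subunit of protein phosphatase 1, 1.20 ± 0.24), Ebp (1.11 ± 0.21), Arpc5l (1.07 ± 0.21), Snrpd3 (0.98 ± 0.17) and Nsmce2 (0.82 ± 0.17) were also higher. Dcdc2b (-2.38 ± 0.35), Trim34a (-1.75 ± 0.39), Recql5os1 (-1.51 ± 0.33), Vps50 (-1.43 ± 0.25) and Cwc15 (-0.86 ± 0.16) were lower. A probe set named for Cks2 was lower by -2.34 ± 0.38, but it is 1 of 3 probe sets with identical values, of which another is annotated to a different gene, so its identity is uncertain.

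That fit called 257 probe sets, 102 higher and 155 lower, and 14 could be named. The balance turned over without infarction array 5 (389 higher, 250 lower), with array weights (913 and 616) and with infarction array 5 counted as sham (282 and 49, with 32 of the 257 among them). Higher calls also outnumbered lower ones without sham array 2 (87 and 83) and with the ENDO arrays alone and array weights (71 and 64). The fit uses 1 spread for all arrays. With the 8 ENDO arrays alone limma called 0, with 2333 at unadjusted p under 0.05, and with a weight per population 93 of the 257 still passed. No named list member passed in ENDO cells over all probe sets, and Mcm2 of the cell cycle list (0.77 ± 0.25, adjusted p = 0.204) passed when adjusted over the list alone, as its sole named member. The other list members owe their names to the authors' TCRM table. List genes that changed in ENDO cells outside the authors' tables could not be seen. Tigit (0.66 ± 0.28), Pdcd1 (0.41 ± 0.30), Il4 (0.25 ± 0.23) and Il21 (-0.13 ± 0.30) had adjusted p between 0.377 and 0.931. In the authors' deposited table for ENDO cells 38 probe sets were higher and 236 lower, 167 had no symbol, and the lowest false discovery rate was 0.0677. The count was 152 without ENDO infarction array 1, 639 without infarction array 5, 51 without sham array 1, 170 without sham array 2 and 117 without sham array 3. Of the named genes Dcdc2b alone passed with each ENDO array left out.

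The last comparison tested whether the response to infarction differed between the populations. The TCRM minus ENDO difference of responses was 3.33 ± 0.42 (log2, SE) for Il21, 3.24 ± 0.47 for Gpm6b and 2.45 ± 0.40 for Tigit, with adjusted p of 0.0117, 0.0177 and 0.0266. Sccpdh (3.11 ± 0.47), Gpr155 (2.60 ± 0.34), Angptl2 (2.15 ± 0.31), Nav2 (2.07 ± 0.21), Csf1 (2.01 ± 0.36), Nt5e (1.99 ± 0.34), Maf (1.83 ± 0.33), Tgfb3 (1.82 ± 0.31) and Il4 (1.79 ± 0.33) also differed. The sizes for Il21 and Sccpdh are uncertain, because their TCRM sham signal lay near or under the filter cutoff. That for Gpm6b is uncertain because its TCRM sham arrays varied widely. Of the 15 named genes that differed, Il21, Gpr155, Angptl2, Nav2, Stfa3 and Art2a-ps passed with each array left out. The other 9 did not: leaving out 1 array ended the call with 13 of the arrays for Il4, 11 for Maf, 10 for Csf1, 9 for Nt5e, 8 for Tgfb3, 6 for Tigit, 4 for Sccpdh, 3 for Cks2 and 1 for Gpm6b. Of the 7 named follicular helper genes 6 differed, and 7 did when adjusted over the list alone, which is not independent evidence because the authors selected them for a TCRM difference on these arrays. Pdcd1 did not pass over all probe sets (1.56 ± 0.43, adjusted p = 0.223).

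In all, 56 probe sets differed, 48 with the higher response in TCRM cells and 8 with the lower. After quantile normalization of all 16 arrays 75 differed, 47 higher and 28 lower. The 193 probe sets that rose in TCRM cells had a median log2 difference of 1.11 there and 0.10 in ENDO cells. In ENDO cells 142 of them (73.6%) were also higher after infarction, against 50.9% of all tested probe sets, and 28 of them differed between populations. As they were chosen for their rise in TCRM cells, their TCRM median is biased upwards. With the number taken as the animal and kept as a fixed block, 0 differed (limma, 2476 at unadjusted p under 0.05), and with a random block 61 did. The count was 30 without ENDO infarction array 3 and 10, 35 and 22 without ENDO sham arrays 1, 2 and 3. It was 24, 12, 23 and 35 without TCRM infarction arrays 1, 2, 4 and 5, and 20 and 32 without TCRM sham arrays 2 and 3.

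**Figure D3:**
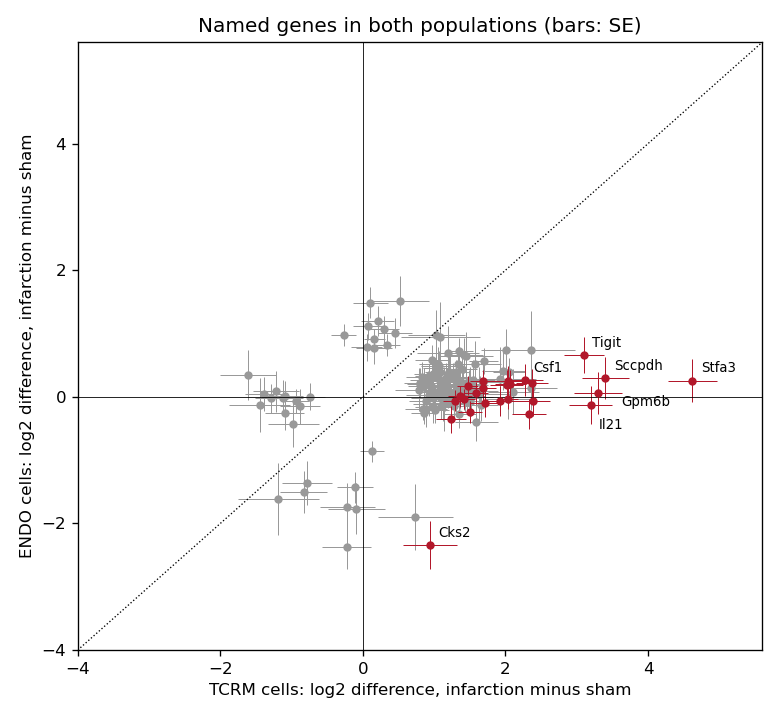
Log2 difference, infarction minus sham, in TCRM cells (horizontal) against ENDO cells (vertical) for the named genes, with SE bars; red points differ between populations at adjusted p under 0.05 and the dotted line marks equal responses. The genes come from the authors' 2-fold tables, so each was selected for a difference in 1 of the populations; Il21 lies at 3.19 and -0.13.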

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

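The test of unequal spread for the ENDO calls, the simulations without any change and the median of the TCRM risers over other splits of the ENDO arrays were chosen after the result was seen. In the groups of 5 arrays, 1 array lay far from the other 4 for 3 of 65 measures in TCRM cells and for 7 of 65 in ENDO cells, where chance gives about 1 in 20. The gap divided by the range was 0.929 for Dnajc9 on TCRM infarction array 1 (8.64 against 8.27 to 8.29), 0.761 for Trim34a on the same array and 0.729 for Vps50 on TCRM infarction array 3. In ENDO cells it was 0.844 for Prdm1, 0.808 for Nkg7 and 0.732 for mt-Tq, each on infarction array 1. It was 0.741 for Mcm2 and 0.711 for Tnfsf8 on infarction array 5, 0.854 for Lad1 on infarction array 2 and 0.712 for Il1r1 on infarction array 3.

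The response to infarction differed between TCRM and ENDO cells for 56 probe sets. The differences on the log2 scale were 4.37 for Stfa3, 3.33 for Il21, 3.28 for Cks2 (1 of 3 probe sets with identical values, identity uncertain), 3.24 for Gpm6b, 3.11 for Sccpdh, 2.60 for Gpr155, 2.46 for Art2a-ps, 2.45 for Tigit and 2.15 for Angptl2. They were 2.07 for Nav2, 2.01 for Csf1, 1.99 for Nt5e, 1.83 for Maf, 1.82 for Tgfb3 and 1.79 for Il4. The sizes for Stfa3, Il21 and Sccpdh are uncertain, because their TCRM sham signal lay under or near the filter cutoff. That for Gpm6b is uncertain because its TCRM sham arrays varied widely.

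Whether the 257 ENDO calls come from a spread shared with the quieter TCRM arrays stays open, since 0 remained with the ENDO arrays alone, which also lowers the degrees of freedom, while 93 remained with a weight per population and 135 were called with the ENDO arrays alone and array weights. In 20 simulations without any change, the shared spread gave at most 43 ENDO calls. The simulated noise was independent between probe sets and held no structure shared across an array, so this is no upper limit for the real arrays. Of the 56 splits of the 8 ENDO arrays, 5 gave as many calls, the real one included, so chance cannot be excluded. The highest other split, which groups infarction arrays 4 and 5 with sham array 3, gave 3166, so the ENDO arrays have a structure other than the operation. Leaving out infarction array 5 and sham array 3 gave 192 calls and lost 143 of the 257, and a part played by these arrays stays open, because leaving out infarction array 5 gave the highest count with each of the 3 sham arrays, so the bound set beforehand, the median of 126 over 15 pairs, decides nothing.

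Rises outnumbered falls among the TCRM calls. Without sham array 3 the share of rises was 89.8%, which argues against that array as the cause. With the 8 TCRM arrays quantile normalized again, where falls went from 26 to 48, the share was 78.8%, between the bounds of 60 and 80 set beforehand, so a part played by scaling stays open, although it was 89.6% with median centring and 86.3% with 16 arrays normalized again. For the number of calls, 1 of 56 splits, the real one, gave 219 and the highest other gave 75. This argues against chance for that number, but 56 splits are too few to exclude it. It does not test the share of rises. A response of myosin-specific cells to infarction stays open as the biological explanation.

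Probe sets that rose in TCRM cells moved less in ENDO cells, although 142 of 193 had the same direction there. The highest ENDO median with 1 ENDO array left out was 0.11. The real median plus the largest of the 55 other splits of the ENDO arrays (0.109) was 0.208. Both lay under the bound of 0.556 set beforehand. That bound comes from the TCRM median, which the choice of these probe sets biases upwards, and the ENDO median itself defines the pattern. The values argue against the larger ENDO spread as the sole cause for these 193 probe sets as a set. They do not exclude a part played by it, because the bias of the TCRM median was not measured. The other splits gave ENDO medians between -0.109 and 0.092. The lowest ratio of the medians was 10.1 while the SDs over probe sets had a ratio of 1.13. This argues against a narrower ENDO signal range as the sole cause, although the TCRM median in that ratio is biased upwards. Of 100 drawn splits 3 gave 56 or more probe sets with a different response, the real one included. The highest other gave 122. That share is under the threshold of 0.05, but with 100 splits drawn it is too imprecise to exclude chance. Only 28 of the 193 risers are among the 56, so this count does not test their smaller movement in ENDO cells. The choice of these probe sets for their TCRM rise and the separate normalization stay open, as does a biological difference between the populations.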

How the results depend on the processing

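Choices that were added after seeing the data are identical probe sets counted once, the population weights, the ENDO fits without arrays or with weights, and scaling within a population. No named gene that passed changed sign in any alternative. Of the named genes that passed, 19 of 27 in TCRM cells, 1 of 13 in ENDO cells and 6 of 15 for the difference kept passing with each array left out. Where no cause is named it was not tested.

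The 219 TCRM calls became 122 (2-fold, adjusted p), 426 (2-fold, unadjusted p), 377 (array weights), 131 (quantile normalization of 16 arrays), 118 (8 arrays alone), 531 (population weights) and 0 (infarction array 5 counted as sham), and 113 to 310 with an array left out. The 257 ENDO calls became 164, 697, 1529 and 442 under the first 4 of these, 0 with the 8 arrays alone, 93 with population weights, 331 with infarction array 5 counted as sham, and 51 to 639 with an array left out. With the ENDO arrays alone, array weights gave 135 and leaving out the outlying pair 0 (limma, 2861 at unadjusted p under 0.05). The 56 differences became 847 (2-fold, unadjusted p), 213 (array weights), 31 (median centring) and 0 (infarction array 5 counted as sham, 3033 at unadjusted p under 0.05), and 10 to 82 with an array left out.

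The replicate block gave 217 TCRM calls, 266 ENDO calls and 61 differences as a random effect, and 0 differences as a fixed effect, which leaves fewer degrees of freedom. In 1 of 8 pairs an array correlated best with its own number.

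Values that turned sign were all of genes that did not pass. With an ENDO array left out, Ccl5 ran from -0.131 to 0.215, Egln3 from -0.003 to 0.261, Il21 from -0.227 to 0.007, Nfil3 from -0.236 to 0.044, Nrp1 from -0.04 to 0.291 and Nt5e from -0.168 to 0.068 in ENDO cells. With a TCRM array left out, Mcm2 ran from -0.081 to 0.36 in TCRM cells. With array weights on 16 and on 8 arrays, the ENDO values were -0.048 and -0.025 for Il4 and 0.023 and 0.006 for Trat1. With infarction array 5 counted as sham they were 0.19 for Nt5e and 0.238 for Trat1. Not run were the tests between populations at 1 time, the camera and fry tests of gene lists, the mean of a gene's probe sets and the pseudocount, as the values are log2 already. The list of T cell receptor variable segments was not analysed either. Signal over background is not known.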

Other observations

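The 26 probe sets that fell had a median log2 difference of -0.76 in TCRM cells and -0.05 in ENDO cells. Among genes in the authors' deposited table for TCRM cells that were lower after infarction, Arhgap20 (-1.61 ± 0.39), Lad1 (-1.22 ± 0.32) and Treml2 (-1.10 ± 0.25) did not pass here (log2, SE, limma's adjusted p between 0.0662 and 0.126). Abhd4, a lipase of N-acyl phospholipid metabolism, rose by 2.07 ± 0.22 in TCRM cells, and its TCRM minus ENDO difference of responses was 1.87 ± 0.31. The naming rule did not take Abhd4 for that comparison, so it is not among the 15 genes above. Its difference was not examined with arrays left out.

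Unnamed probe sets 17200645 and 17207747 rose in TCRM cells by 2.31 and 2.02 on the log2 scale, and 17547988 and 17403473 changed by -1.05 and -1.03. Of the probe sets in the authors' deposited tables, 60.9% had no symbol for ENDO cells and 7.1% for TCRM cells. In a test chosen after the data were seen, with the same relabelling of the numbered animals in both populations, 2 of 56 splits gave 56 or more probe sets with a different response, the real one included, and the highest other gave 57.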
